A study of Bos taurus with 20 samples.

How the data were processed

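Messenger RNA of frozen-thawed spermatozoa from Holstein-Friesian bulls was measured by sequencing, with 10 libraries labelled high fertility (High) and 10 labelled low fertility (Low). Each library came from 1 bull and from semen pooled over 3 ejaculates, so a replicate is a bull and the spread between libraries holds both animal and technical variation. Per the labels' protocols, RNA was purified with Trizol with a step against genomic DNA, and libraries were made with the NEBNext kit for single cells and low RNA input. Bulls were assigned to a fertility class from a statistical model, per the labels. The numbers in the sample names run over both groups without repeating, so nothing pairs a High bull with a Low bull, and no batch or date is used here.

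The submitters' processing notes name FastQC 0.11.8, cutadapt 2.6, STAR 2.6.1, R 3.4, edgeR 3.5 and the genome build UMD3.1, without saying which step each served. The counting tool, its strand setting and the annotation release are not given in the sources used here. The deposited values are a normalised signal per gene rather than raw counts: in each column every value is a whole number of reads multiplied by 1 factor for that library. The column sums differ, and their geometric mean over the 20 columns is 1000000, which is what CPM values with normalisation factors that multiply to 1 give. The share of values that came out whole, within 0.1 of a read, was 100% in every library when the smallest step of a column was taken as 1 read. Depth in reads comes from this division. In 13 of the columns too few low values exist for an independent check of that step, so their read totals rest on it. No test of counts was run on them. In all 20 columns the largest deviation from a whole number was 0.000788 of a read. A test of counts on all libraries was thus left undone, not shown to be impossible.

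The columns of High replicate 9 and Low replicate 8 are identical for every gene. Since the same profile stands under opposite fertility labels, it was used in neither group, which leaves 18 libraries, 9 per group. This choice was made after the values were seen, and the alternatives with both columns, or with the profile in 1 group, are given in the closing section. The design, 16 gene lists and those alternatives not listed in the closing section as chosen later were fixed before the data were examined. The planned main test was edgeR's quasi-likelihood test on counts over all 20 libraries. Because the values are normalised, the main test was instead limma 3.58.1 with a mean-variance trend (R 4.3.3) on log2(value + 1), for genes with a value of at least 1 in at least 9 libraries, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. Differences are High minus Low on the log2(value + 1) scale, which understates the change of low genes, and where a gene is 0 in many libraries the difference mainly reflects in how many libraries it was seen. As alternatives, edgeR 4.0.16 and DESeq2 1.42.0 were run on the recovered reads of the 7 libraries that passed the check (4 High and 3 Low). The restriction to these 7 libraries followed from the values and was not fixed in advance. Surrogate variables came from sva 3.50.0.

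The table holds 27607 Ensembl gene identifiers and does not pair them with symbols. None of them (0) matched the reference gene table used here (37063 genes), which lists no Ensembl identifiers. The 16 gene lists, written as symbols, were therefore not tested, and neither were shares of reads from mitochondrial, ribosomal or marker genes. The rule for named genes asked for symbols and ranked genes by p within each direction, among those with a difference of group medians of the same sign. It was applied to identifiers, for 1 gene per direction. A further gene per direction was chosen after its values were seen, as the gene detected in the most libraries of 1 group and in 0 of the other.

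Library measures (read total, number of genes above 0, number of genes at 1 or more, share of the 10 most abundant genes) and the distance of each library to its own group (1 minus the Spearman correlation over the tested genes, averaged over the group) were compared by two-sided exact permutation tests over all 48620 assignments of 9 and 9 libraries. Intervals of the differences are 95% bootstrap intervals from 10000 draws. Detection per gene was compared by Fisher's exact test. Correlations across libraries have permutation p-values, exact within a group and from 100000 permutations over 18 libraries, adjusted by Benjamini-Hochberg over 9 relations (Python 3.11.15, scipy 1.17.1, numpy 2.4.6). Read totals ran from 9426708 to 49451216 reads per library. For a gene at 0 in a library, a floor of 3 reads was used for bounds on fold differences. The reads carry no molecular identifiers that are used here, so PCR copies are not independent molecules, and such bounds cover counting error only.

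The limma step was tested on simulated data and on the real values with the groups mixed, each with genes multiplied by known folds. Alternatives tried were other scalings, filters, pseudocounts, covariates, library weights, a robust variance prior, the count tests above, and leaving out each library.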

Results

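Ejaculated spermatozoa carry little RNA and are transcriptionally silent, so their transcripts are mostly left from spermatogenesis. The series asks whether the mRNA content of spermatozoa differs between bulls of high and low fertility. It holds 20 libraries of Holstein-Friesian bulls, 10 labelled High and 10 labelled Low, each from 3 pooled ejaculates of 1 bull. The profiles of High replicate 9 and Low replicate 8 were identical for every gene and were left out, so the comparisons rest on 9 High and 9 Low libraries. Values are a normalised signal close to CPM, and genes are known here only by their Ensembl identifiers.

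A small set of abundant transcripts was shared by all bulls, and most other genes were seen in only some of them. Of 27607 genes in the table, 8173 were above 0 in at least 1 of the 18 libraries, 200 were above 0 in all 18, and 171 had a value of at least 1 in all 18. These 171 genes made up 65.0% ± 4.26 (SD, n = 18) of the summed values of a library, with a range of 56.7% to 71.5%. At the other end, 2790 genes were above 0 in exactly 1 library. Those single-library genes were not read at trace level: their median value was 40.2, and 89.9% of them had over 100 reads in that library. The most abundant gene of a library took between 4.10% and 12.3% of its summed values, and 6 different genes held that place across the 18 libraries.

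The number of genes detected ranged 5.25-fold between bulls, from 708 in High replicate 2 to 3720 in Low replicate 18. It was 1956 ± 798 (SD, n = 9) in High and 2293 ± 1027 (SD, n = 9) in Low. The difference of -337 genes (95% bootstrap interval -1142 to 458) was smaller than the SD of either group. The group means were not detectably different (two-sided exact permutation p = 0.444, adjusted over 4 measures 0.839). The 10 most abundant genes took 28.7% ± 2.77 of the signal in High and 29.4% ± 2.48 in Low (SD, n = 9 each, exact permutation p = 0.630, adjusted 0.839). Genes at a value of 1 or more numbered 1869 ± 771 in High and 2209 ± 1011 in Low (SD, n = 9 each, exact permutation p = 0.430, adjusted 0.839). Read totals, in units of 1000000 reads (M), were 17.2 ± 12.6 M in High and 16.8 ± 4.51 M in Low (SD, n = 9 each, exact permutation p = 0.975, adjusted 0.975), and the direction of that difference depended on High replicate 14 at 49.5 M, without which it was -3.68 M (exact permutation p = 0.0868).

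**Figure D1:**
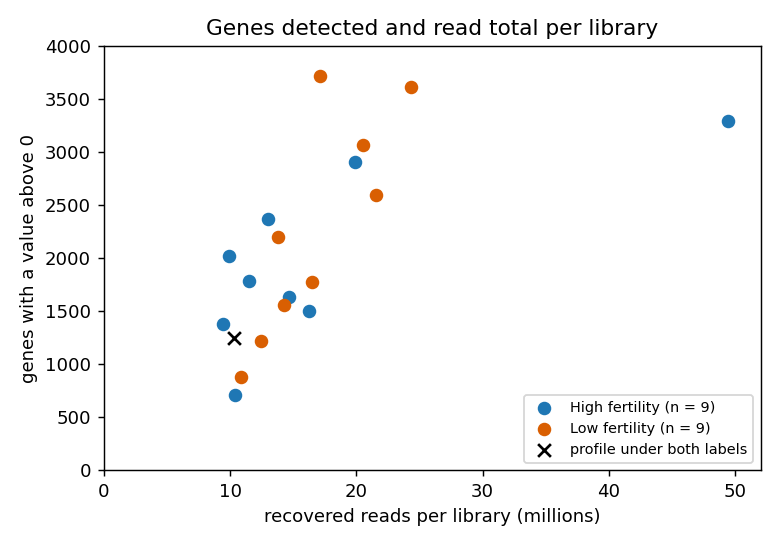
Number of genes with a value above 0 (y axis) against recovered reads in M (x axis), 1 point per library, blue for High (n = 9), orange for Low (n = 9) and a cross for the profile that stands under both labels (1247 genes). Libraries of both groups spread over the range from 708 to 3720 genes, and High replicate 14 lies apart at 49.5 M reads.

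Libraries with more reads had more genes detected, although thinning to the smallest read total left 98.2% to 100% of each library's genes. Over the 18 libraries Pearson's r was 0.623 (permutation p = 0.00097, adjusted 0.00218) and Spearman's rho 0.744 (permutation p = 0.0006, adjusted 0.00135), and r was 0.693 without High replicate 14 and Low replicate 1, the libraries farthest from the median read total. Within Low, r was 0.810 (exact permutation p = 0.0101, adjusted 0.0152) and rho 0.833 (exact permutation p = 0.00827, adjusted 0.0149), with r = 0.644 without Low replicates 1 and 11. Within High, r was 0.732 (exact permutation p = 0.00756, adjusted 0.0136) and rho 0.617 (exact permutation p = 0.0857, adjusted 0.0964), and r fell to 0.176 without High replicates 14 and 6, so the relation in High rests on those libraries.

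Genes of middling abundance were listed at 0 in many libraries, while the most abundant genes were seen in every one. Among genes with a mean of 100 to 1000 in the other 17 libraries, the share listed at 0 ranged from 2.28% in Low replicate 18 to 65.5% in High replicate 2, with a median of 22.3%, although at least 866 reads per gene corresponded to such a mean in every library. The median share at 0 was 93.2% for genes with a mean of 1 to 10, 74.8% for 10 to 100 and 0.727% for 1000 to 10000. Of the genes with a mean over 10000, 0% were listed at 0 in any library. Where a gene was seen, reads were plentiful, with a median per detected gene between 804.5 and 5647 reads across libraries.

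**Figure D2:**
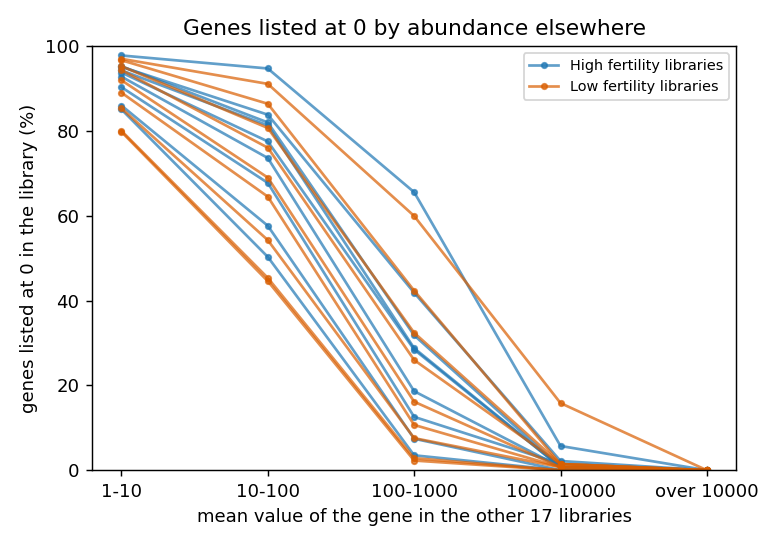
Share of genes listed at 0 in a library (y axis, percent) by the mean value of the gene in the other 17 libraries (x axis, in bins), 1 line per library, blue for High and orange for Low. The lines part most between 100 and 1000, where they run from 2.28% to 65.5%, and meet at 0 above 10000.

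No tested gene passed the adjusted threshold for a difference between High and Low bulls. Of the 1458 genes with a value of at least 1 in at least 9 libraries, 0 passed an adjusted p of 0.05 in limma (smallest adjusted p = 0.994). At an unadjusted p under 0.05 there were 40 genes, 13 higher and 27 lower in High, where chance gives 72.9. Of these 40 genes, 21 were detected in at least 4 more libraries of one group than of the other, against 46 among all 1458, and 3 were detected in all 18 libraries. The median difference over all tested genes was -0.25 on the log2 scale, and lay between -0.31 and -0.20 under the other scalings tried. In no gene (0) were the values of the groups without overlap. Chance gives this in only 0.00411% of genes, so a count of 0 among 1458 genes says little.

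Among the 171 genes with a value of at least 1 in every bull, differences were measured more closely. They ran from -1.26 to 1.30 log2 with a median of 0.07. In the limma fit over all 1458 genes, 3 of these had an unadjusted p under 0.05 (2 higher in High). In that fit 0 passed when adjusted over these 171 alone (smallest adjusted p = 0.976). A separate limma fit on the 171 genes alone gave 7 at an unadjusted p under 0.05 and 0 adjusted (smallest adjusted p = 0.833). In the fit over all 1458 genes, the median 95% interval of the 171 reached 1.23 log2 to either side, or 2.35-fold. The interval lay within 2 log2 units of 0 for 127 of the 171 genes and within 1 log2 unit for 9. Over all 1458 genes the median interval reached 3.17 log2 to either side.

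**Figure D3:**
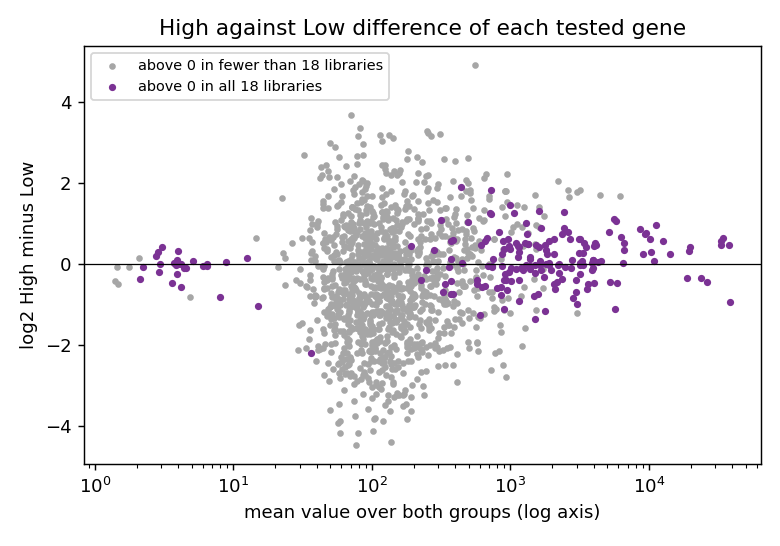
Difference between High and Low on the log2(value + 1) scale (y axis) against the mean value over both groups (x axis, log scale), 1 point per tested gene, with the genes above 0 in all 18 libraries in purple and the others in grey. None of the 1458 genes passed the adjusted threshold (0 genes), and the widest differences belong to genes missing from some libraries.

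Other tests also bear on the count of 0. Fisher's exact test of how many libraries detected each of the 1458 genes gave 0 at an adjusted p under 0.05 and 6 at an unadjusted p under 0.05, all 6 detected more often in Low (smallest unadjusted exact p = 0.0152). That count of 0 says little, since the smallest exact p that 9 against 9 libraries can give is 4.11e-05, which becomes 0.0600 when a single one of the 1458 genes reaches it. On the recovered reads of 7 libraries (4 High, 3 Low; 3079 genes), edgeR's quasi-likelihood test gave 0 genes at an adjusted p under 0.05 and 121 at an unadjusted one, while DESeq2's Wald test gave 105 genes, 34 of them higher in High. In 97 of those 105 genes all libraries of one group were at 0 reads, and limma on the same 7 libraries gave 0. Detection was uneven among these libraries, with 3065 to 3720 genes in the 3 Low and 1785 to 3297 in the 4 High. Whether this led to the calls was not tested. With real values, mixed groups and 1458 genes, the limma test recovered 0.4% of genes changed 2-fold, 5.6% 4-fold, 19.2% 16-fold and 25.4% 64-fold. Multiplying left every 0 at 0. Among genes at 1 or more in all libraries it recovered 1.7% at 2-fold, 42% at 4-fold and 92.2% at 16-fold. On simulated normal log2 values with the genes' own means and SDs, it recovered 10% at 4-fold and 39.8% at 16-fold. Among genes at 1 or more in all libraries these were 50% and 100%. In both cases each fold was given to 500 genes over 10 runs, with many genes changed together in a run. The adjustment is looser then, so recovery of a single changed gene may be lower.

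The genes given by identifier showed how uneven detection was between bulls. ENSBTAG00000031579, first by the rule among genes higher in High, was detected in 7 of 9 High and 3 of 9 Low bulls, with a mean value of 990.3 ± 1311 (SD, n = 9) in High and 125 ± 299 (SD, n = 9) in Low. Its difference was 4.91 log2 (SE 1.90, 95% interval 1.07 to 8.76), with an unadjusted limma p of 0.0138 and an adjusted p of 0.994. ENSBTAG00000032253, first among genes lower in High, was detected in 2 of 9 High and 8 of 9 Low bulls, with means of 13.3 ± 37.5 and 141 ± 225 (SD, n = 9 each). Its difference was -4.48 log2 (SE 1.33, 95% interval -7.17 to -1.79), with an unadjusted limma p of 0.00179 and an adjusted p of 0.994. Neither difference passed the threshold once p was adjusted over all tested genes, although neither unadjusted 95% interval included equal levels. These means depended on single libraries: for ENSBTAG00000031579 they were 619 without High replicate 14 and 26.9 without Low replicate 13, and for ENSBTAG00000032253 they were 0.855 without High replicate 6 and 69.4 without Low replicate 11 (n = 8 each). The size of the differences depended on the setting, from 3.43 (pseudocount 10) to 8.03 log2 (limma on 7 libraries) for ENSBTAG00000031579 and from -6.69 (pseudocount 0.1) to -1.10 log2 (DESeq2 on 7 libraries) for ENSBTAG00000032253.

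A further pair of genes, singled out after their values were seen, was detected in one group alone. ENSBTAG00000021661 was at 0 in all 9 High libraries and detected in 8 of 9 Low libraries, at 34.8 to 169 (450 to 2943 reads) where seen, with a Low mean of 80.5 ± 52.5 (SD, n = 9). Against a floor of 3 reads per library this would be 354-fold lower in High. That floor covers counting error only. Genes of similar mean were often listed at 0, with a median share of 74.8% per library, so a 0 here does not bound the level of the gene. Fisher's exact p was 0.000411, and 1 when adjusted over the 8173 genes detected, where even a single gene split 9 against 0 would reach only 0.336. ENSBTAG00000021039 was detected in 7 of 9 High libraries, at 24.5 to 267 (220 to 2714 reads), and was at 0 in all 9 Low libraries, with a High mean of 69.9 ± 91.5 (SD, n = 9). Against the same floor this would be 365-fold higher in High, with the same limits (Fisher's exact p = 0.00226, adjusted 1). Without High replicate 16 its High mean was 45.3 ± 57.9 (SD, n = 8) and the difference against that floor 236-fold. Both were at 0 in the profile that stands under both labels. Both were seen in fewer than 9 libraries and so lay outside the 1458 genes. With a minimum of 8 libraries (1698 genes), limma gave ENSBTAG00000021661 a difference of -5.64 log2 (SE 1.12, adjusted p = 0.0223). That minimum equals the number of libraries in which the gene was seen. Over 27 other settings, all conditional on that minimum, its adjusted p ran from 0.000736 to 0.452, under 0.05 in 16 of them. Its difference was -2.84 log2 with a pseudocount of 10 and -8.58 log2 with 0.1. The adjusted p was 0.0419 with no filter (8173 genes), and ran from 0.106 to 0.911 with minimums from 1 to 7 libraries. With a minimum of 7 libraries (1992 genes), limma gave ENSBTAG00000021039 a difference of 4.56 log2 (SE 1.11, adjusted p = 0.214). That minimum again equals the number of libraries in which the gene was seen. Its adjusted p ran from 0.0980 to 0.999 over 27 other settings with that minimum, under 0.05 in 0 of them. Its difference was 2.19 log2 with a pseudocount of 10 and 7.12 log2 with 0.1.

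**Figure D4:**
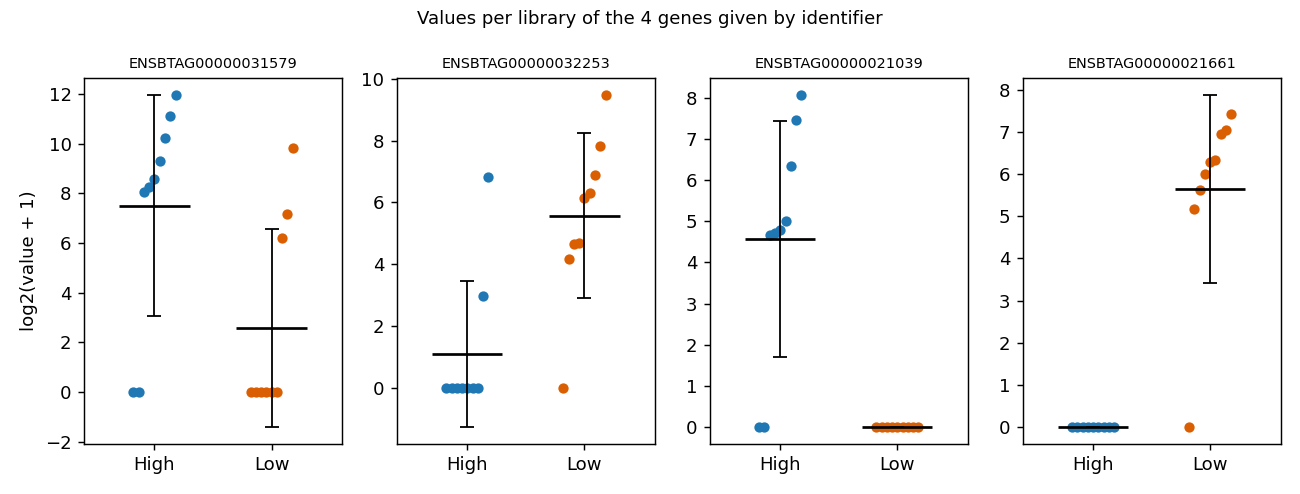
Values of the 4 genes given by identifier on the log2(value + 1) scale (y axis), 1 point per library, with the group mean (horizontal bar) and SD (vertical bar) for High (n = 9, blue) and Low (n = 9, orange). ENSBTAG00000021661 is at 0 in all 9 High libraries and above 0 in 8 of 9 Low libraries, and ENSBTAG00000021039 is at 0 in all 9 Low libraries.

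Bulls of one fertility class were not detectably more alike than bulls of different classes. Spearman correlations between libraries over the tested genes ran from 0.222 to 0.675 with a median of 0.478, and their means were 0.479 within High, 0.466 within Low and 0.471 between the groups. The within-group mean exceeded the between-group mean by 0.000849 (one-sided exact permutation p = 0.379). The mean distance of a bull to its own group was 0.521 ± 0.0351 in High and 0.534 ± 0.0715 in Low (SD, n = 9 each), a difference of -0.0130 (two-sided exact permutation p = 0.838). Its direction rested on single libraries, as it was 0.0289 without Low replicate 11, 0.00283 without Low replicate 7 and 0.00621 without High replicate 14. The first principal component held 22.7% of the variance, and its group means were not detectably different (exact permutation p = 0.534). Nor were those of the second component, with 10.9% of the variance (exact permutation p = 0.253). The first component followed the number of genes detected, with r = 0.942 and rho = 0.992 over 18 libraries (permutation p = 1e-05 for each, the smallest these permutations can give; adjusted 6.2e-05 and 4.5e-05) and r = 0.951 without Low replicates 18 and 1. The same held within High (r = 0.944, exact permutation p = 1.38e-05, and rho = 1, exact permutation p = 5.51e-06). It also held within Low (r = 0.945, exact permutation p = 7.72e-05, and rho = 0.983, exact permutation p = 4.96e-05). Both measures come from the same values, zeros included, so these p-values do not relate independent quantities.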

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

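Of the tests in this part, the one on the shared profile was chosen after the result was seen. In 16 groups of 9 libraries (4 library measures, the distance to the own group, the share of the genes at 1 or more in all libraries and 2 named genes, in each group), the highest or lowest library was compared with the others. Chance sets a library apart in about 1 in 20 such groups where values are spread roughly normally, a rate that does not hold for the 2 named genes, whose values are skewed and often 0. High replicate 14 stood far above the other High libraries with 49.5 M reads (M, 1000000 reads). High replicate 6 stood below them in the share of its 10 most abundant genes, at 22.5%. For ENSBTAG00000031579, Low replicate 13 stood far above the other Low libraries at 912. For ENSBTAG00000032253, High replicate 6 stood above the other High libraries at 113 and Low replicate 11 above the other Low libraries at 711.

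The profile that stands under both High replicate 9 and Low replicate 8 held 1247 detected genes and was used in neither group of the comparisons, so it is given here. If its column had been copied after normalisation, the geometric mean of the column sums would be 1000000 with the profile counted once. With the profile counted once the mean was 1014662, and it was 1000000 with all 20 columns, which argues against a copy made after normalisation. The remaining candidate explanations are that 1 library entered the count table under both names before normalisation, or that it carries a wrong name in 1 of the groups. The tables hold no value that says which bull it belongs to, and no biological explanation was tested.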

How the results depend on the processing

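Among the tests here, those chosen after the data were seen are the minimums of 1 to 8 libraries, the pseudocounts, library weights, the number of detected genes and the first 2 surrogate variables as covariates, Fisher's test, the genes at 1 or more in all libraries, the placements of the identical profile, and edgeR and limma on 7 libraries. Of 24 alternatives for the comparison of all genes other than leaving out a library, 21 gave 0 genes at an adjusted p under 0.05, as did leaving out each of the 18 libraries. The exceptions were no filter on low values (1 gene, adjusted p = 0.0419), a minimum of 8 libraries (1 gene, adjusted p = 0.0223), both ENSBTAG00000021661, and DESeq2 on 7 libraries (105 genes). That gene was not called with minimums from 1 to 7 libraries (adjusted p 0.106 to 0.911). At a pseudocount of 1 its difference stayed at -5.64 log2 under each of these filters, while its SE was 0.917 with no filter, 1.12 with a minimum of 8 and 1.24 to 1.56 with 1 to 7. With the minimum of 8, the adjusted p of ENSBTAG00000021661 rose above 0.05 when any High library was left out (up to 0.148), with a pseudocount of 10 (0.0628) and with a robust variance prior (0.452). For DESeq2 the cause was not tested. That test was planned, but its restriction to 7 libraries was set after the values were seen. The count at an unadjusted p under 0.05 ran from 7 to 142 over the limma alternatives other than those on 7 libraries, and from 26 to 73 on leaving out a library. It was 142 with no filter, 102 with a minimum of 5 libraries and 100 with library weights. The 7 came from a separate fit on only the genes at 1 or more in all 18 libraries. It was 23 with all 20 columns, 52 with the identical profile as High only and 48 as Low only. Of the omissions, it was 26 without Low replicate 1, 73 without Low replicate 7, 69 without High replicate 6 and 67 without Low replicate 20.

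The difference in read totals reversed with medians (-3.46 M, exact permutation p = 0.220) and ran from -3.68 to 1.32 M on leaving out a library. It was -0.389 without Low replicate 11, -0.0281 without Low replicate 19 and -0.189 without Low replicate 20. The difference in the share of the 10 most abundant genes ran from -1.15 to 0.159 percentage points, positive without High replicate 6. The difference in spread ran from -0.0374 to 0.0289, and was positive without Low replicate 11 (0.0289), Low replicate 7 (0.00283) or High replicate 14 (0.00621). The difference in genes detected ran from -513 without Low replicate 11 to -158 without Low replicate 18. For genes at a value of 1 or more it ran from -513 to -162 without the same libraries. None of these passed a threshold. The cause was not tested beyond the library left out. Not run were limma-voom with quality weights (library weights were used), edgeR's robust fit on all libraries (a robust limma prior was used), the alternatives for gene lists, and upper-quartile scaling over all detected genes, whose upper quartile is 0 in several libraries (it was taken over the tested genes). No paired analysis was possible because no replicate number occurs in both groups.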

Other observations

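Of the tests in this part, those of fertility class as a source of the gene numbers and of the splits by detection were chosen after the results were seen. The pattern weighed first is the 5.25-fold range in the number of genes detected. Thinned to 9426708 reads, the smallest total, each library kept 98.2% to 100% of its genes. Low replicate 18 still had 3701 genes and the range was 5.24-fold. These values argue against the number of reads as the source of more than a small part of the range. A low number of RNA molecules entering amplification is a candidate explanation. It predicts that libraries with fewer genes scatter more about the others on the genes at 1 or more in all libraries, and rho was -0.521 (permutation p = 0.0291, adjusted 0.0400), though r was -0.356 (permutation p = 0.147, adjusted 0.166) and -0.695 without Low replicates 18 and 1. Fertility class is not the source of the range as a whole, which was 4.66-fold within High (708 to 3297 genes) and 4.23-fold within Low (879 to 3720), though a smaller part of it by class stays open.

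That relation was rho = -0.733 (exact permutation p = 0.0311, adjusted 0.0400) and r = -0.708 (exact permutation p = 0.0323, adjusted 0.0415) within High, and r was -0.588 without High replicates 14 and 6. Within Low it was rho = -0.417 (exact permutation p = 0.270, adjusted 0.270) and r = -0.252 (exact permutation p = 0.510, adjusted 0.510), and r was -0.782 without Low replicates 18 and 1.

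The 40 genes at an unadjusted p under 0.05 do not exceed what other divisions of the same libraries give. Of 100 splits of the 18 libraries into 9 and 9, the real one included, 84 gave at least 40 such genes, and the highest other split gave 217, so chance cannot be excluded. A split with several times the real count may reflect structure among the libraries, but no split's count was compared with a measure of the libraries.

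The 2 genes seen in at least 7 more libraries of one group than of the other, ENSBTAG00000021661 and ENSBTAG00000021039, were weighed in the same way. Of 24310 splits, 8790 (36.2%) gave at least 2 such genes, with 78 in the highest other split, so chance cannot be excluded for their number. Whether either gene differs with fertility class in other bulls was not tested.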
